A study of Fusarium oxysporum with 12 samples.

How the data were processed

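Fusarium oxysporum, a filamentous fungus whose strains include plant pathogens, was profiled on 2-channel spotted microarrays, 12 arrays in all. Per the labels, channel 1 of every array held total RNA of a control culture and channel 2 held RNA of a culture starved of carbon (6 arrays) or of nitrogen (6 arrays), with replicate numbers 1 to 6 in each group. The labels name the starved cultures Fol, an abbreviation not expanded here. Medium, length of starvation, strain, dyes and the array's spot content were not given in the sources used here.

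The deposited values were log2 ratios, 1 per spot and array. The log base was read from the values: 1000 times the antilog to base 2 was a whole number within 0.01 for 12721 of the 12729 values (99.9%). The scanner, background correction, normalization, centring method and direction of the ratio were not given in the sources used here. Array means lay between -0.003 and 0.009 and array medians between -0.109 and -0.003, so the values had been centred near 0 before deposit. The direction is likely starved over control, since the labels put the control in channel 1 and the starved RNA in channel 2 on all arrays and a test-over-reference ratio is the usual form. All pairs of arrays correlated above 0 (lowest r = 0.13 across spots), so no array ran against the others. Signal intensities were not used here, so the number of arrays limits the precision.

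The table held 1061 spots: 1056 clone IDs, whose form gives a plate (11 plates) and a well (96 per plate), 2 spots named for a solvent (dmso, dmso1), which were left out of the tests, and 3 spots with other names (EF, EF1 and fmk1). The files do not pair the clone IDs with genes, and 0 of the IDs were found in a table of 16502 Fusarium oxysporum genes (assembly ASM1308505v1). The 17 gene lists fixed in advance therefore had no members and were not tested. Clones are counted, not genes, since several clones can come from 1 gene.

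Log2 ratios were used as deposited, without further centring or scaling. The 1059 spots with a value on 4 or more of the 6 arrays of each group were fitted in limma 3.58.1 (R 4.3.3; lmFit, eBayes) with a mean for each starvation, all 12 arrays sharing 1 estimate of the spread. Each mean was tested against 0, and the difference of the means was tested as a contrast. These limma tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The control RNA served as the reference on each array, so a ratio tested against 0 leaves out the control's own spread. No label says that arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Only 3 values were missing, all on nitrogen array 3, and no 2 arrays held identical values.

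Same-numbered carbon and nitrogen arrays were checked for pairing. The correlation of their deviations from the group means was 0.22, 0.25, 0.40, 0.40, 0.38 and 0.33 for numbers 1 to 6, above 0.1 for every pair. With the median of each well column subtracted from each array it was lower, at 0.15, 0.14, 0.25, 0.18, 0.33 and 0.35. Each carbon array then correlated most with its own number, against 5 of 6 as deposited. The numbers were therefore taken to pair the arrays. This pairing comes from the values, since the labels do not say what the numbers share. The replicate number was therefore tried as a block.

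The rule for named clones was set before the data were examined: with no gene names, the 2 highest and the 2 lowest clones of each comparison among those past the threshold, with the same sign on all arrays or, for carbon against nitrogen, with no overlap between the groups' arrays. The spots fmk1, EF and EF1 and the clones Fol6B7 and Fol1C3 fall outside this rule and were chosen after their values were seen. The deposited log2 ratios were also re-fitted after centring each array on its median, scaling, quantile normalization, other filters, array weights, other eBayes settings, stricter thresholds, a fit on each group alone and leaving out each array. After the data were seen, the fit was repeated with well-column medians subtracted, with a term for odd-numbered against even-numbered arrays, on odd or even arrays alone, with adjacent arrays averaged and without arrays 3 and 4.

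The fit was tested on simulated data with the observed spread and 1059 clones, 50 of them changed at each size. For carbon starvation against control it recovered 52% of clones changed by 0.5 on the log2 scale and 96% of those changed by 1, and 5.43% of its calls were unchanged clones. For carbon against nitrogen it recovered 18% and 86% at these sizes, with 0.66% of calls unchanged. With noise shared by adjacent arrays the shares of unchanged clones among calls were 6.42% and 6.67%. That noise had a correlation of 0.305, estimated from the values as deposited. Noise shared by same-numbered carbon and nitrogen arrays, for which the values gave a correlation of 0.414, was left out. These shares may therefore not hold for the data. Figures were drawn with matplotlib 3.10.9.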

Results

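Transcript levels of Fusarium oxysporum under carbon starvation and under nitrogen starvation were each compared with control RNA on 6 arrays, 12 in all. Each value is the log2 ratio of a clone on 1 array, and positive values likely mean more transcript in the starved culture. Arrays of the same starvation mostly resembled each other more than arrays of different starvations. Nitrogen arrays 3 and 4 were the clearest exceptions. Each correlated most with the carbon array of its own number (0.656 and 0.648), and at 0.59 at most with another nitrogen array. Carbon arrays 3 and 4 were also close to these nitrogen arrays. Carbon array 3 correlated higher only with carbon array 1 (0.658), and carbon array 4 only with carbon array 2 (0.687). The correlation across spots ranged from 0.50 to 0.90 within carbon starvation (median 0.66), from 0.27 to 0.87 within nitrogen starvation (median 0.57) and from 0.13 to 0.66 between them (median 0.26). The 2 solvent-named spots give a background. The mean log2 ratio of dmso was -0.003 ± 0.181 (SD, n = 6) under carbon and 0.076 ± 0.229 under nitrogen starvation, and that of dmso1 was 0.24 ± 0.21 and 0.17 ± 0.37. Single arrays ranged from -0.31 to 0.35 for dmso and from -0.36 to 0.72 for dmso1.

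**Figure D1:**
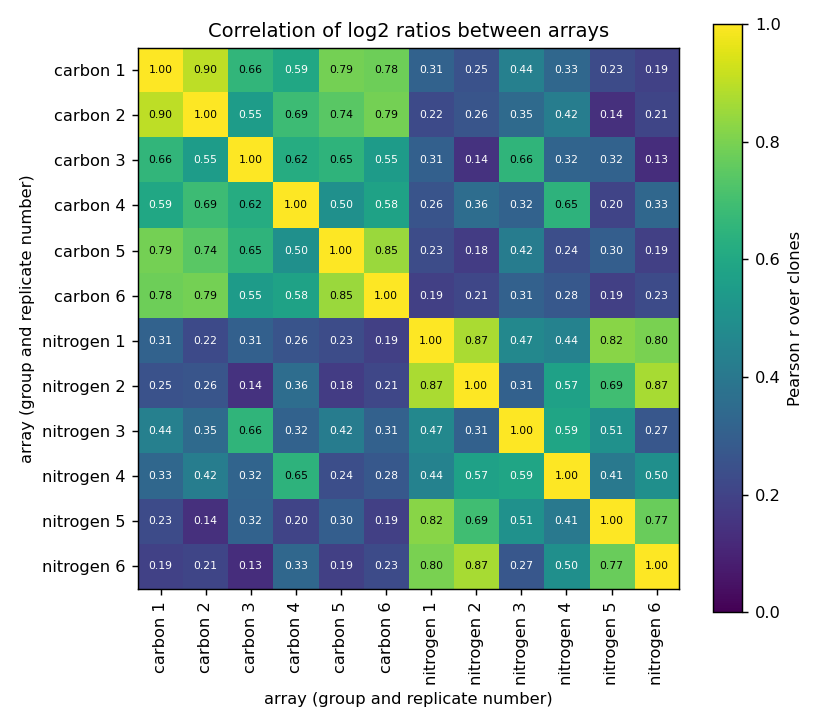
Pearson correlation of the log2 ratios across spots for each pair of the 12 arrays, with the array's starvation and replicate number on both axes and r as colour and number. Arrays of 1 starvation correlate at 0.27 or above and arrays of different starvations at 0.66 or below, with the highest values between starvations on arrays 3 and 4.

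Under carbon starvation the largest ratios were positive. Fol10D11 had the highest mean log2 ratio, 3.26 ± 0.70 (SD, n = 6), a 9.55-fold ratio (limma adjusted p = 1.40e-07). Fol10D12 followed at 2.97 ± 0.63, a 7.81-fold ratio (limma adjusted p = 1.65e-07). These 2 clones lie in neighbouring wells and their values correlated at 0.978 over the arrays, so they may come from 1 gene. Both also passed the threshold under nitrogen starvation, at 0.83 ± 0.59 and 0.81 ± 0.62. Fol1F2 had the lowest, -2.64 ± 0.92, a 6.25-fold ratio in the negative direction (limma adjusted p = 9.64e-07), and Fol8B2 was at -2.18 ± 0.74 (limma adjusted p = 2.03e-06). These 4 clones had the same sign on all 6 carbon arrays. Their p-values treat the 6 arrays as separate, although arrays with adjacent numbers deviated together. Over the re-fits the highest limma adjusted p was 0.0016 for Fol10D11, 0.0017 for Fol10D12, 0.0014 for Fol1F2 and 0.0020 for Fol8B2.

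Of 1059 spots tested, 348 (32.9%) passed the threshold under carbon starvation, 157 positive and 191 negative. The positive calls had a median log2 ratio of 1.04 and the negative calls one of -0.69. Among the calls, 148 had an absolute log2 ratio of 1 or more, 82 of them positive, and 35 reached 2 or more, 27 of them positive. The sign was the same on all 6 arrays for 254 of the calls. Averaging arrays 1 with 2, 3 with 4 and 5 with 6, whose values deviated together, left 228 calls. Odd-numbered arrays alone gave 264 calls and even-numbered arrays alone 178.

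Nitrogen starvation likewise gave larger positive than negative ratios. Fol7G5 had the highest mean log2 ratio, 3.51 ± 0.63 (SD, n = 6), an 11.4-fold ratio (limma adjusted p = 2.48e-08), and Fol6H3 was at 3.16 ± 0.94, an 8.95-fold ratio (limma adjusted p = 1.58e-06). Both also passed the threshold under carbon starvation, at 1.33 ± 0.58 and 1.20 ± 0.68. The lowest were Fol5A7 at -2.07 ± 1.14 (limma adjusted p = 8.56e-05) and Fol9F8 at -1.95 ± 0.43 (limma adjusted p = 2.04e-07). Each of the 4 kept 1 sign on all 6 nitrogen arrays. The highest limma adjusted p over the re-fits was 3.29e-04 for Fol7G5, 0.0034 for Fol6H3, 0.0241 for Fol5A7 and 0.0013 for Fol9F8.

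Under nitrogen starvation 291 of 1059 spots (27.5%) passed the threshold, 141 positive and 150 negative, with median log2 ratios of 1.07 and -0.65. An absolute log2 ratio of 1 or more was reached by 105 of them, 77 positive and 28 negative, and one of 2 or more by 16, of which 15 were positive. The balance of the directions depended on the zero point. With each array centred on its median, 160 of 267 calls were positive and 107 negative. With well-column medians removed, 183 of 323 were positive and 140 negative. Averaging adjacent arrays left 165 calls, and odd-numbered and even-numbered arrays alone gave 160 and 156. Whether the number of calls differed between the starvations was not tested.

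The spot named fmk1, after the mitogen-activated protein kinase gene that Fusarium oxysporum needs for pathogenicity on plants, was negative on all 12 arrays. Its mean log2 ratio was -0.69 ± 0.14 (SD, n = 6) under carbon starvation (limma adjusted p = 4.76e-04) and -0.67 ± 0.34 under nitrogen starvation (limma adjusted p = 8.86e-04), ratios of 1.62-fold and 1.60-fold. The difference between the starvations was -0.02 (95% interval -0.40 to 0.36). On odd-numbered arrays alone its nitrogen value was -0.48 and no longer passed the threshold.

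The spots EF and EF1 were negative on average but varied widely. EF was at -1.79 ± 1.37 under carbon (limma adjusted p = 0.0159) and -1.95 ± 1.71 under nitrogen starvation (limma adjusted p = 0.0121), and EF1 at -1.75 ± 1.35 (limma adjusted p = 0.0106) and -1.88 ± 1.48 (limma adjusted p = 0.0087). EF values of adjacent arrays resembled each other: carbon arrays 1 and 2 had -3.38 and -3.28, whereas carbon arrays 5 and 6 had -0.20 and -0.46. Without carbon array 1 or 2, EF under carbon starvation missed the threshold (limma adjusted p = 0.0713 and 0.0641), as did EF1 without carbon array 1 (limma adjusted p = 0.0511). With adjacent arrays averaged, or on even-numbered arrays alone, neither spot passed under either starvation. On odd-numbered arrays alone EF missed the threshold under both starvations and EF1 under nitrogen starvation. Without arrays 3 and 4 the nitrogen values were -1.01 for EF and -1.14 for EF1 (limma adjusted p = 0.177 and 0.107).

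**Figure D2:**
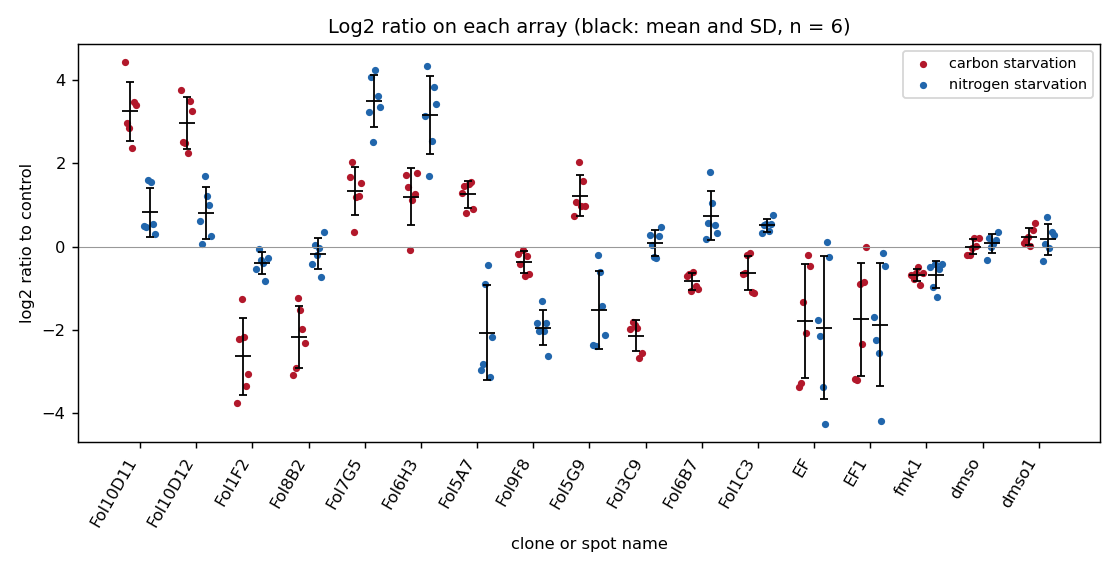
Log2 ratio to control on each array for the named clones and spots, with carbon arrays in red and nitrogen arrays in blue, and the mean and SD (n = 6) in black. Fol10D11 and Fol10D12 lie highest under carbon starvation, Fol7G5 and Fol6H3 under nitrogen starvation, and EF and EF1 spread from near 0 to -4.28 and -4.20.

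Carbon and nitrogen starvation differed for 233 of the 1059 spots (22.0%) when the difference itself was tested. Fol5A7 differed most: it was positive on all carbon arrays, at 1.26 ± 0.32 (SD, n = 6), and negative on all nitrogen arrays, a difference of 3.33 (SE 0.42, limma adjusted p = 9.13e-05). Fol5G9 was at 1.23 ± 0.48 under carbon and -1.53 ± 0.94 under nitrogen starvation, a difference of 2.75 (SE 0.38, limma adjusted p = 1.52e-04). In the other direction, Fol1F2 had a difference of -2.24 (SE 0.34, limma adjusted p = 3.44e-04), with -0.40 ± 0.26 under nitrogen starvation. Fol3C9 had a difference of -2.23 (SE 0.21, limma adjusted p = 1.87e-05), with -2.15 ± 0.37 under carbon and 0.08 ± 0.30 under nitrogen starvation. Over the re-fits the highest limma adjusted p of the difference was 0.0247 for Fol5A7, 0.0217 for Fol5G9, 0.0427 for Fol1F2 and 0.0215 for Fol3C9.

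Of the 233, 105 had the higher log2 ratio under carbon and 128 under nitrogen starvation, and these numbers would change places if the ratio were control over starved. Their median differences were 1.33 and -1.31. Differences of 1 or more were reached by 168. With the replicate number as a fixed block, which takes the pairing of same-numbered arrays into account, 319 spots differed. Averaging adjacent arrays left 115, odd-numbered and even-numbered arrays alone gave 98 and 110, and leaving out arrays 3 and 4, on which the starvations differed least, gave 371.

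**Figure D3:**
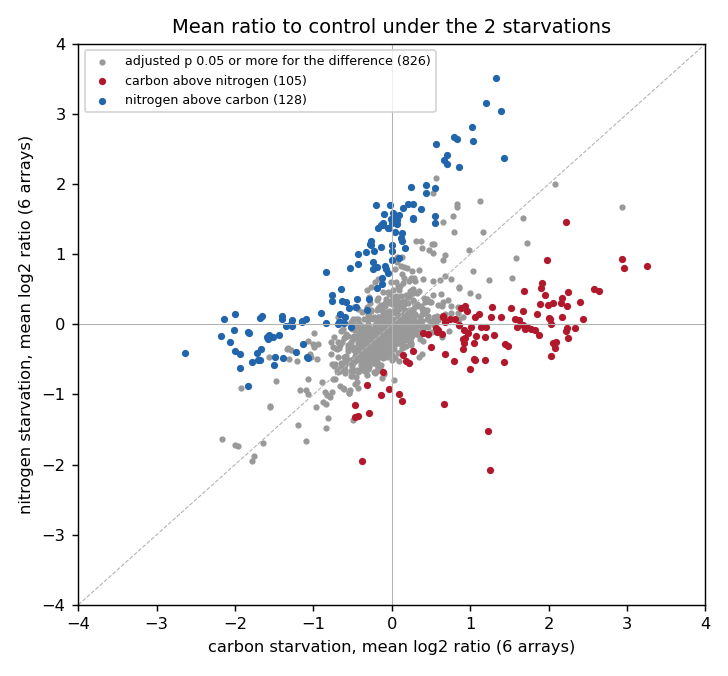
Mean log2 ratio under carbon starvation (x axis) against nitrogen starvation (y axis), 6 arrays each, 1 point per spot; the dashed line marks equal ratios. The 105 red spots had the higher ratio under carbon and the 128 blue spots under nitrogen starvation, as deposited, while grey spots did not pass the test of the difference.

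Some spots had ratios in the same direction under both starvations. Called in the same direction were 122 spots, 42 positive and 80 negative, the latter with fmk1, EF and EF1 among them, where independent lists of these lengths would share 20.9 and 27.1. With each array centred on its median, 50 were positive and 56 negative, and with well-column medians removed 61 and 73. With an absolute log2 ratio of 1 or more 13 were positive and 10 negative. Unchanged groups were simulated by subtracting the group means and turning the signs of same-numbered arrays together (31 patterns). They shared a median of 0 calls and at most 14. Subtracting the means also takes away the effects that fill both lists, so this count is no test of sharing. The simulated groups leave out any offset common to all arrays as well. A control RNA shared by both starvations or a constant bias of 1 channel at a spot would give such an offset. Part of the overlap may therefore come from the control or from such a bias. The mean log2 ratios of the starvations correlated across spots at r = 0.41 (rho = 0.50), where spots are not independent replicates. The same simulated groups gave a median r of 0.33 (0.07 to 0.74) but a median covariance of only 0.0126, against 0.185 observed. With carbon means from 3 arrays set against nitrogen means from the 3 other numbers, r averaged 0.35 over 20 splits. Within adjacent numbers, r was 0.28 for arrays 1 and 2, 0.61 for 3 and 4 and 0.25 for 5 and 6. The shared calls fell to 44 with adjacent arrays averaged, and were 57 on odd-numbered and 41 on even-numbered arrays.

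Opposite calls were few. Of 7 clones called in opposite directions, 5 were positive under carbon and negative under nitrogen starvation, Fol5A7 and Fol5G9 among them. The other 2 were Fol6B7, at -0.84 ± 0.20 under carbon and 0.74 ± 0.59 under nitrogen starvation, and Fol1C3, at -0.64 ± 0.41 and 0.51 ± 0.15 (SD, n = 6). With adjacent arrays averaged, Fol5A7 under carbon starvation and Fol6B7 and Fol1C3 under nitrogen starvation no longer passed (limma adjusted p = 0.0564, 0.0588 and 0.109), while the difference between the starvations still passed for Fol5A7, Fol5G9, Fol6B7 and Fol1C3. On even-numbered arrays alone the carbon calls of Fol5A7, Fol5G9 and Fol1C3 ended (limma adjusted p = 0.0716, 0.0734 and 0.0721), on odd-numbered arrays alone that of Fol1C3 (limma adjusted p = 0.0518), and on either set the nitrogen calls of Fol6B7 and Fol1C3.

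Positive calls differed between the starvations more often than negative ones. Of the spots positive under carbon starvation, 89 of 157 (56.7%) were farther from 0 than under nitrogen starvation by the test of the difference, against 57 of 191 negative ones (29.8%; Fisher's exact test, two-sided p = 4.83e-07). Of the spots positive under nitrogen starvation, 71 of 141 (50.4%) were farther from 0 than under carbon starvation, against 19 of 150 negative ones (12.7%; Fisher's exact test, two-sided p = 2.29e-12). Spots are not independent replicates, so these p-values may be too small. Positive calls also lay farther from 0, which makes a difference easier to detect.

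The median ratio of the clones in a well column depended on whether an array's number was odd or even. In column 12 the median log2 ratio averaged 0.32 on odd-numbered and -0.30 on even-numbered arrays. Both groups held 3 arrays of each kind. The mean of the odd and even profiles was not flat either, at -0.19 in column 5.

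**Figure D4:**
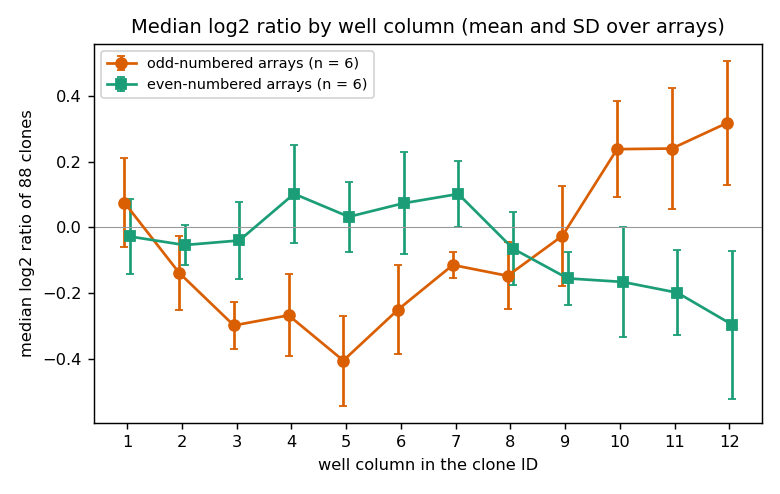
Median log2 ratio of the 88 clones of each well column, as the mean and SD over the 6 odd-numbered and the 6 even-numbered arrays. The odd arrays rise and the even arrays fall towards column 12.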

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

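The checks on arrays 3 and 4 for a control of their own and for exchanged labels, the exchanges of single arrays and the patterns of adjacent pairs were chosen after the results were seen; the mixing test, the drawn splits and the sign patterns were set before theirs were seen.

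The effect of starvation differed between carbon and nitrogen for 233 spots by limma's test of the difference. The named clones among them, with carbon minus nitrogen differences on the log2 scale, were Fol10D11 (2.43), Fol10D12 (2.16), Fol1F2 (-2.24), Fol8B2 (-2.01), Fol7G5 (-2.18), Fol6H3 (-1.96), Fol5A7 (3.33), Fol9F8 (1.58), Fol5G9 (2.75), Fol3C9 (-2.23), Fol6B7 (-1.58) and Fol1C3 (-1.15). Fol6H3 on carbon array 3 lay far below the 5 other carbon arrays, at -0.0755. It was the 1 outlying array in 34 groups of 6 values examined, and chance gives about 1 in 20.

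Turning the signs of single arrays, with the deposited values and their group means kept, gave no count as high as the real one: 1 of 32 sign patterns or splits, the real one, reached 348 calls for carbon starvation (highest other 188), and likewise 1 of 32 for the 291 nitrogen calls (highest other 114) and the 122 shared calls (highest other 3). Chance can be excluded for the carbon and nitrogen counts only if the 6 arrays vary separately. For the shared count these patterns are no test of sharing, since turned signs also shorten or empty both lists it is drawn from. Adjacent arrays deviated together, and with such pairs kept whole there are only 4 sign patterns, too few for a share under 0.05 (highest others 3, 0 and 0).

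For the 233 differing spots, 2 of 100 drawn splits of the 12 arrays gave as many, the real one and another with 264, a share under which chance can be excluded only if the arrays vary separately. With adjacent arrays kept together there are only 10 splits, too few for a share under 0.05 (highest other 12). The split with 264 calls exchanged carbon array 4 with nitrogen array 3. Of all 36 exchanges of 1 carbon with 1 nitrogen array, only this one reached 233; the other 3 exchanges among arrays 3 and 4 gave 82 to 141 and all exchanges with other arrays 29 or fewer. Because whether a draw holds this split is a matter of the draw, the 36 exchanges say more than the drawn share. The exchange also puts 4 odd-numbered arrays in the carbon group instead of 3: with well-column medians removed it gave 210 calls against 278 for the real groups, and with a term for odd against even arrays 243 against 261. Of the 32 splits that part every same-numbered pair, 1, the real one, reached 233 (highest other 106).

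Carbon and nitrogen arrays numbered 3 and 4 differed less from each other than the other arrays. On the 100 clones that differed most on the other arrays, the difference on arrays 3 and 4 had a slope of 0.349. The slope was 1.22 for arrays 1 and 2 and 1.14 for 5 and 6. For these pairs the other arrays include 3 and 4, which raises their slopes, so part of the contrast is built in. A control RNA shared by arrays 3 and 4 would cancel in the difference and leave a slope near 1. It is therefore argued against as the whole cause. Labels exchanged between the arrays of 1 number would turn its slope negative, whereas the lower slope of numbers 3 and 4 was 0.345. An exchange of carbon array 4 with nitrogen array 3 would leave slopes near 0, whereas numbers 3 and 4 had 0.345 and 0.354, which speaks against it. So does carbon array 4 with column medians removed. It correlated at 0.71 with the carbon mean of arrays 1, 2, 5 and 6 and at 0.33 with their nitrogen mean. Nitrogen array 3, treated likewise, was nearly as close to carbon (0.40) as to nitrogen (0.46). Partial mixing of the starved RNAs stays open: regressed on both means of the other arrays, nitrogen arrays 3 and 4 had a coefficient of 0.261 for carbon, but carbon arrays only 0.121 for nitrogen, and a weaker starvation of these cultures may also account for it and was not tested.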

How the results depend on the processing

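All alternatives that average adjacent arrays, use odd or even arrays alone, add an odd-even term, subtract well-column medians or leave out arrays 3 and 4 were chosen after the data were seen. Of 137 re-computed counts and correlations, 118 stayed within 1.5 times of the main value or within its spread. For r that spread was 0.196, the SD over the 6 same-numbered pairs, so the r of 0.26 given below counted as within it. This is a lax rule for r, since single arrays vary more than means of 6. The pairs numbered 3 and 4, at 0.66 and 0.65, also widened the SD. Many of the 137 left out 1 array and kept its adjacent partner, so this share is a weak measure of stability. Median centring also moved the balance of positive and negative calls, for nitrogen starvation and the shared calls as the report gives it, to 163 and 167 for carbon starvation and to 93 and 132 for the differing spots. Removing well-column medians gave 385 carbon, 323 nitrogen, 278 differing and 134 shared calls. The counts that moved did so as follows, and the cause was not tested except where fewer arrays or a stricter rule make it plain. Array weights gave 448 calls for nitrogen and 376 for carbon against nitrogen starvation. An absolute log2 ratio of 1 or more left 148 carbon, 105 nitrogen and 23 shared calls (13 positive, 10 negative), and an adjusted p under 0.01 left 177 nitrogen and 47 shared calls. Averaging adjacent arrays left 228 carbon, 165 nitrogen, 115 differing and 44 shared calls. Odd-numbered arrays alone gave 160 nitrogen, 98 differing and 57 shared calls, and even-numbered arrays alone 178, 156, 110 and 41 for carbon, nitrogen, differing and shared calls. Without arrays 3 and 4, 371 spots differed, and r between the starvations was 0.26. Leaving out 1 array at a time gave 270 to 363 carbon, 226 to 294 nitrogen, 193 to 254 differing and 96 to 116 shared calls, with r from 0.35 to 0.43. With the replicate number as a random block carbon and nitrogen starvation gave 349 and 289 calls, and with it as a fixed block 319 spots differed; neither moved these counts by over 1.5 times or ended a call of a named clone. Of 861 re-computed values of named clones and spots, 38 lost their call, most of them EF, EF1, Fol6B7 and Fol1C3, and no called value changed sign. Dropping or averaging arrays could not turn the sign of the named clones, whose arrays all had 1 sign or whose groups did not overlap. The uncalled differences of EF, EF1 and fmk1 between the starvations, also among the 861, had no call to lose. They did change sign under some alternatives, EF ranging from -0.82 to 0.58. A minimum of 2 arrays removed no clone, and the gene list alternatives were not run, since no list had members. Signal over background was not analysed here, so the number of arrays is the only stated limit on precision.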

Other observations

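The tests of clone content, of exchanged channels, of column bias among neighbours, of the remaining neighbour pairs, of adjacent arrays, of the shared calls and of shuffled plate rows and columns were chosen after the results were seen; those of batches, near-identical neighbours and plates were set before theirs were seen.

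Shared calls split by direction. Of the 42 spots positive under both starvations, 20 (47.6%) differed in size between them, against 7 of the 80 negative under both (8.75%; Fisher's exact test, two-sided p = 3.81e-06). Without fmk1, EF and EF1 the negative share was 7 of 77 clones (9.09%; Fisher's exact test, two-sided p = 4.40e-06). The shared positive calls had a median absolute log2 ratio of 1.10 and the negative ones 0.68, so a difference was easier to detect among the positive. With adjacent arrays averaged, the shares were 58.8% of 17 and 3.70% of 27. The negative share moved to 18.0% with array weights, 2.50% with trend and robust eBayes settings, and 0% with an absolute log2 ratio of 1 or more, an adjusted p under 0.01 or odd-numbered arrays alone. It was 16.0% of 75 without arrays 3 and 4 and 4.76% of 21 on even-numbered arrays. Without single arrays it was 4.17% (carbon array 2), 5.00% (nitrogen array 1), 5.80% (nitrogen array 2) and 4.23% (nitrogen array 4).

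Odd-numbered and even-numbered arrays differed along the well columns. Of the 88 clones in column 12, 87 were higher on odd arrays (median difference 0.61), and of the 88 in column 5, 87 were lower (median -0.41). The content of the wells is argued against as the cause, since the odd and even column profiles ran opposite (r = -0.64 on carbon and -0.82 on nitrogen arrays). A regional bias of 1 colour channel with channels exchanged between odd and even arrays may account for it: 11 of the 12 arrays followed the turned profile, the remaining one correlating at -0.27, which leaves it open. Printing or scanning batches also stay open, the mean profile having 0.441 times the SD of the odd-even difference divided by 2, and no biological explanation was tested.

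Clones in neighbouring wells of a row had like ratios under carbon starvation, whereas under nitrogen starvation neighbours in a column did (r = 0.128, permutation p = 1e-04), with weaker likeness in a row (r = 0.076, adjusted permutation p = 0.0271) and none detected in a column under carbon starvation (r = 0.006, permutation p = 0.861). For carbon rows, column bias is argued against, since with column medians removed the correlation of neighbours was 0.131 (permutation p = 1e-04, the smallest the permutations can give). Near-identical neighbours were more common than in shuffles, 15 of 968 pairs with a profile correlation above 0.9 against at most 11 in 1000 shuffles, Fol10D11 and Fol10D12 among them (0.978). They are argued against as the whole cause: the other pairs still correlated at 0.0918 (one-sided permutation p = 0.0011). Clones of 1 gene placed side by side could underlie this, which needs the clone sequences.

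Arrays with adjacent numbers deviated together. With column medians removed, the pairs 1 and 2, 3 and 4, and 5 and 6 had a mean correlation of deviations of 0.459 for carbon and 0.517 for nitrogen arrays, the highest of the 15 possible pairings in both groups; as deposited they ranked 1 of 15 and 2 of 15.

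Called clones were spread unevenly over the 11 plates in 1 of 6 classes when neighbouring wells were kept together. With clones shuffled singly, which makes p too small where neighbours are alike, the lowest adjusted permutation p, 0.00252, was for clones with the higher deposited ratio under nitrogen starvation, 19 on plate 3 and 4 on plate 11 where 11.6 were expected. With whole plate rows or whole plate columns shuffled instead, its adjusted permutation p was 4.80e-04 and 0.0177, while that of the 5 other classes was 0.0717 or more.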
